A study of Homo sapiens with 6 samples.

How the data were processed

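The data are RNA sequencing profiles of TC-71, a human Ewing sarcoma cell line, treated for 16 h with BEZ235 or with its solvent dimethyl sulfoxide (DMSO). Each group held 3 libraries, and per the labels' protocols the RNA came from biological replicates, purified on columns and treated with DNase. How RNA was selected for the libraries and whether strand was kept are not given in the sources used here.

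The authors deposited a table of normalized gene read counts, a signal that is never negative, with 1 column per library. Per the submitters' processing notes, FastQC, Picard, SAMtools, STAR 2.4.0, DESeq and the genome build hg38 were used; their roles are not stated. Per the file headers, rows are genes of the FASTDB annotation with hg38 coordinates. The table had 48114 rows, of which 21404 carried no gene symbol, 349 carried several symbols, 17 lay on the mitochondrial genome and 2 carried a number in place of a symbol. Columns named as controls were matched to the DMSO samples by their number, since these were the only control samples. The counting rule is not given in the sources used here, so rows that overlap another row or an antisense gene, and genes with near-identical copies, may share reads. Among the named genes ALPK2, FUT1, FGF21, SREBF1, TMEM97, ERBB2, HEXA, MAP1LC3B, PAPPA, ACTA2, IER3, TP53I3, TSC2, EIF4B, NEFM, H2BC11, CD68, MUC1, ESAM, FLI1 and CCND1 overlap another expressed row.

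The values of each deposited column were whole multiples of 1 step, the worth of 1 read after the authors' scaling, which ran from 0.835 to 1.16 normalized counts. Dividing by it gave whole reads for 100.0% of values, within a tolerance of 0.01 normalized counts. The recovered reads summed to 184790722 to 233767211 per library. At this depth 3 reads, the limit that a count of 0 allows, corresponded to 2.50 to 3.47 normalized counts. Counting intervals (95%, exact binomial) and the limit of 3 reads, which is not one of them, cover counting error only, since reads without molecular identifiers are not independent molecules.

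Genes with a normalized count of at least 10 in at least 3 of the 6 libraries were tested, 23923 in all. The test was limma with a mean-variance trend (limma 3.58.1, R 4.3.3) on log2(normalized count + 1), with the group as the only term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Fold changes are on this log2 scale, which understates the change of genes with low counts. The count test edgeR (4.0.16, quasi-likelihood) on the recovered reads called 15744 genes and DESeq2 (1.42.0) called 15706, against 15863 for the limma test; both were alternatives. With 3 libraries against 3, an exact permutation test of a single gene cannot give a p below 0.1, so no such test was used.

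Before the data were examined, 27 gene lists were fixed: targets and processes connected with PI3K and mTOR signalling, growth and stress, genes reported to respond to the EWSR1-FLI1 fusion, lists that bear on RNA quality, and markers of blood, epithelial, fibroblast and endothelial cells. Lists with at least 5 tested members entered camera with a preset correlation of 0.01 between genes, adjusted over the 26 lists so tested. The list of mitochondrial protein genes matched no symbol in the table and was not tested; the rows of the mitochondrial genome were named by position with GENCODE v29. A symbol was matched to a row that carries it among others for 8 members, so that PPAN was counted with P2RY11, GRWD1 with KCNJ14 and H3C4 with H2AC7. The alternatives were camera with an estimated correlation and fry, whose p tests whether genes of a list move, on balance, in 1 direction.

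Genes named in the text follow a rule fixed at the same time. It takes the 8 largest rises and 8 largest falls among genes past the threshold with a symbol, no overlap between the groups and a mean of at least 100 in the higher group. It also takes up to 3 members of each list with the smallest adjusted p in the list's main direction and 1 in the other direction. EWSR1, FLI1, IGF1R, IRS2, MYC, CCND1, PIK3CA, MTOR, SREBF1, SREBF2, ATF4, DDIT4, NR0B1 and NKX2-2 are given whatever their values. Some genes that the rule selects are not named in the text. Genes outside the rule are identified as chosen after their values were seen.

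The alternatives were TMM scaling, quantile normalization, pseudocounts of 0.5 and 10, no filter, a filter at 50, limma without the trend, the replicate number as a block, leaving out each library, both count tests and both other list tests. These were set before the data were examined; total-count scaling was added after the data were seen. The scripts were tested on simulated data with 200 changed genes and a gene list shifted as a whole, with 23468 simulated genes passing the filter. There limma recovered 67.2% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 100% of those changed 4-fold. It called 0.03% of unchanged genes. In the real data 66.3% of tested genes were called, a far larger share than was changed in the simulation. The 200 changed genes were also drawn only from genes outside the lists with a mean normalized count of at least 50. These rates may therefore not hold for the real comparison, and the recovery rates do not cover genes with lower counts. Figures and matched gene sets were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.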

Results

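Gene expression was measured by RNA sequencing in TC-71 cells, an Ewing sarcoma line, after 16 h with BEZ235, an inhibitor of the lipid kinase PI3K and the growth-controlling kinase mTOR, or with DMSO alone. The comparison asks which transcripts differ when this signalling is inhibited. Each group had 3 libraries. The recovered reads amounted to 186274074, 219228026 and 221626548 in the BEZ235 libraries and 190769924, 184790722 and 233767211 in the DMSO libraries. Within a group, log2 values of library pairs correlated across genes with Pearson's r of 0.982 to 0.987, against 0.927 to 0.939 between groups. Counts of libraries in the same group differed by more than sampling noise (mean chi-square per gene of 20.02 to 210.8), so no library was a copy of another. The first principal component held 73.3% of the variance and separated the groups. Rows of the mitochondrial genome took 0.51 to 0.71% of the normalized counts in BEZ235 libraries and 2.82 to 3.55% in DMSO libraries. Ribosomal RNA rows took 5.67 to 7.40% and 7.10 to 10.8%.

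Of 23923 genes tested, 15863 (66.3%) differed between BEZ235 and DMSO, 7912 of them higher and 7951 lower in BEZ235. A change of at least 2-fold was seen for 6303 genes, 3039 higher and 3264 lower. The groups did not overlap for 70.9% of tested genes, against 10% by chance. The largest rises with BEZ235 were those of SLC12A3, ADAMTSL2, TGFBI, BTBD17, CIBAR2, MGAM, DKK1 and CHGA. BTBD17 rose from a normalized count of 35.7 ± 13.7 to 2019 ± 207 (SD, n = 3) and CHGA, a secretory granule protein of neuroendocrine cells, from 15.0 ± 2.73 to 624 ± 19.1. DKK1, a secreted inhibitor of Wnt signalling, reached 157 ± 37.0 from 4.57 ± 4.01. SLC12A3, a sodium chloride cotransporter, had 416 reads over the BEZ235 libraries and 1 read in DMSO, a DMSO to BEZ235 ratio of 0.00232 (95% counting interval 5.85e-05 to 0.013).

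The largest falls were those of ESRP1, S100P, CHAC1, ALPK2, FUT1, INHBE, FGF21 and TAC1. ESRP1, an epithelial splicing regulator (FASTDB gene GSHG0041855, hg38 chromosome 8, 94641074 to 94707466), fell from 18015 ± 497 to 22.1 ± 9.24, a log2 fold change of -9.70 (SE 0.258, limma adjusted p = 3.95e-10). CHAC1, a glutathione-degrading enzyme on chromosome 15 (40953471 to 40956512), fell from 34897 ± 3153 to 113 ± 26.0, a log2 fold change of -8.28 (SE 0.137). S100P went from 1033 ± 319 to 1.54 ± 2.67, and INHBE from 4515 ± 535 to 31.4 ± 5.22. FGF21 had 1 read in BEZ235 libraries, a DMSO to BEZ235 ratio of 486 (95% counting interval 86.8 to 1.92e+04). TAC1 had none, against 379 reads in DMSO, which is at least 122-fold lower when set against 3 reads over the group; the 95% counting interval of its ratio, which includes the error of the DMSO reads, starts at 98.5. FUT1 and FGF21 lie inside the row of FTL, and ALPK2 overlaps an unnamed row, so their reads could be shared. The plot of named genes shows their values per library.

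**Figure D1:**
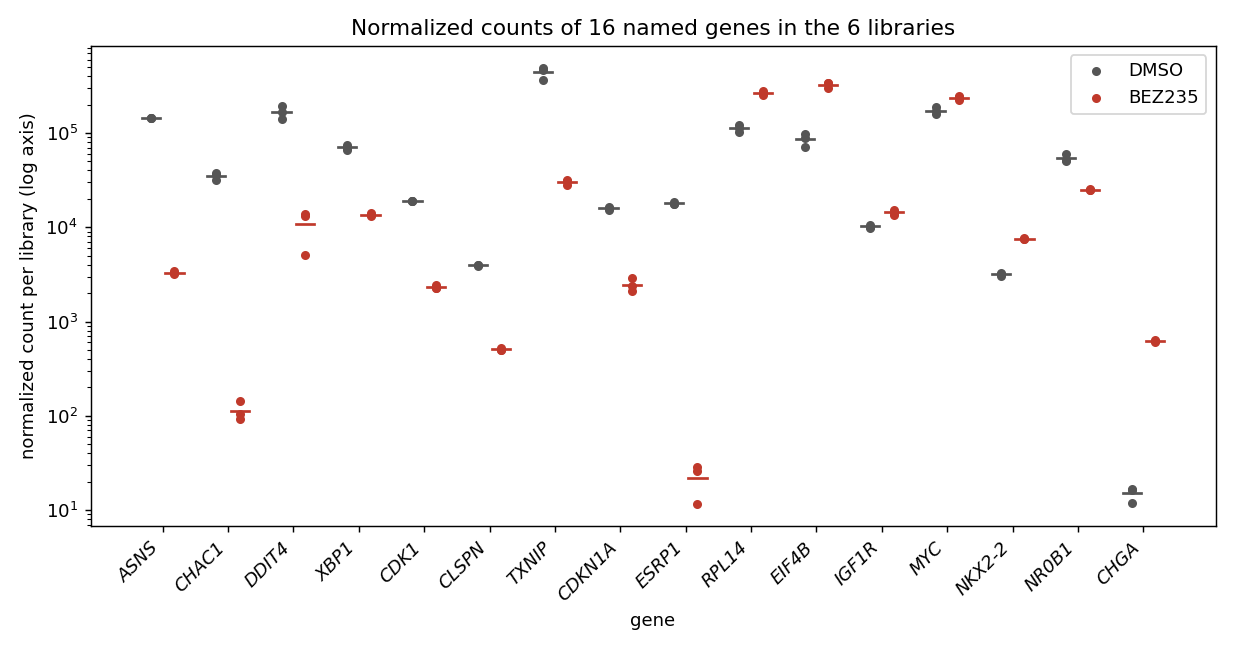
Normalized counts (log axis) of 16 named genes in each DMSO (grey) and BEZ235 (red) library, where points are libraries and bars are means of 3. ESRP1 lies at 18015 in DMSO and 22.1 in BEZ235 on average, and CHGA at 15.0 and 624.

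The list of ATF4, the transcription factor of the amino acid response, and its targets fell together: 36 of 37 tested members, ATF4 among them, were lower with BEZ235, 30 of them by at least 2-fold, with a median log2 fold change of -2.26, and without ATF4 35 of 36 were lower (camera adjusted p = 3.53e-19; adjusted p = 0.326 with an estimated correlation). ASNS, asparagine synthetase, fell from 144425 ± 1488 to 3292 ± 137, and PSAT1 of serine synthesis from 106930 ± 7023 to 6978 ± 184. ATF4 itself changed less, with a log2 fold change of -0.43 (SE 0.069). The unfolded protein response list, which shares stress genes with this response, had 22 of 25 members lower and 2 higher, or 23 and 2 adjusted over the list alone (camera adjusted p = 4.8e-10; adjusted p = 0.326 with an estimated correlation). The chaperone HYOU1 had a log2 fold change of -2.72 (SE 0.047), HERPUD1 of -2.66 and the transcription factor XBP1 of -2.37. The lectin chaperone CANX rose, with a log2 fold change of 0.61 (SE 0.072). DDIT4, an inhibitor of mTOR complex activity, fell from 168291 ± 26727 to 10728 ± 4853.

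Cell cycle transcripts were lower with BEZ235. All 53 tested G2/M and mitosis genes fell, 50 by at least 2-fold, with a median log2 fold change of -2.06 (camera adjusted p = 8.79e-26; adjusted p = 0.326 with an estimated correlation). CDK1, the mitotic kinase, fell from 19062 ± 101 to 2332 ± 79.3, and the kinetochore genes NUF2 and SPC24 had log2 fold changes of -3.21 (SE 0.058) and -2.95 (SE 0.063). Of 52 genes of the G1/S transition and DNA replication, 43 fell and 3 rose, or 44 and 3 adjusted over the list alone (camera adjusted p = 1.76e-11; adjusted p = 0.319 with an estimated correlation). CLSPN, E2F2 and ASF1B had log2 fold changes of -2.95, -3.22 and -2.74, while the primase gene PRIM1 rose by 0.67 (SE 0.059). Genes raised by p53 or DNA damage were also mostly lower, with 20 of 29 down and 7 up (camera adjusted p = 0.00118; adjusted p = 0.319 with an estimated correlation). GADD45A, SESN2 and the cyclin-dependent kinase inhibitor CDKN1A fell, CDKN1A from 15873 ± 462 to 2469 ± 388, whereas TP53I3 rose from 856 ± 198 to 4845 ± 376. TP53I3 lies within the row of FAM228B, which had a log2 fold change of 1.72. Of 18 replication-dependent histone genes, 8 rose and 3 fell (camera adjusted p = 0.122; 0.038 without DMSO replicate 1). H2AC6, H2BC12 and H2BC5 rose, and H2BC11 fell.

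Ribosomal protein transcripts and most of those of ribosome biogenesis were higher. Of the 81 genes of the ribosomal protein list, which also holds EEF1A1, EEF1B2, EEF2 and TPT1, 80 rose and 0 fell, and without these 4 genes 76 of 77 rose and 0 fell, with a median log2 fold change of 0.64 either way (camera adjusted p = 1.56e-17; adjusted p = 0.741 with an estimated correlation). Quantile normalization lowered this median to 0.35 and placed some members below 0. RPL14 rose from 112619 ± 9347 to 263897 ± 12553, RPS9 had a log2 fold change of 1.15 (SE 0.072) and RPL29 of 1.02 (SE 0.067); these genes have processed pseudogenes with which reads could be shared. Of 58 genes of ribosome biogenesis, 40 rose and 7 fell, where PPAN and GRWD1 share their rows with P2RY11 and KCNJ14 (camera adjusted p = 8.95e-07; adjusted p = 0.741 with an estimated correlation). NOB1 rose from 8965 ± 1032 to 33786 ± 2032, POLR1E and WDR74 also rose, and the helicase DDX21 fell by 0.81 on the log2 scale. Genes of the PI3K, AKT and mTOR pathway moved both ways, 22 up and 22 down of 53 (camera adjusted p = 0.962), with a median of 0.08, which was -0.02 with total-count scaling, and a mean of -0.11. The initiation factors EIF4A1 and EIF4B rose, EIF4B from 85916 ± 13546 to 324411 ± 21015, as did TSC2, an upstream inhibitor of mTOR, and SESN2 fell by 3.45. EIF4B and TSC2 overlap other rows. MTOR had a log2 fold change of -0.60 (SE 0.068) and PIK3CA of -0.20 (SE 0.054).

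Known FOXO targets, which include receptor genes repressed by AKT, were lower more often than higher: 20 of 36 fell and 7 rose (camera adjusted p = 0.00399; adjusted p = 0.741 with an estimated correlation). SESN3, GADD45A and TXNIP fell, TXNIP from 440657 ± 64020 to 30243 ± 1797, and the receptor gene ERBB2 rose with a log2 fold change of 0.92 (SE 0.055). The insulin-like growth factor receptor IGF1R and the adaptor IRS2 rose by less, 0.50 (SE 0.058) and 0.43 (SE 0.055) on the log2 scale. Autophagy genes had 23 of 42 members lower and 10 higher, or 24 and 11 adjusted over the list alone (camera adjusted p = 0.0238; adjusted p = 0.822 with an estimated correlation). Without BEZ235 replicate 3 the camera adjusted p was 0.0584. TFE3, MAP1LC3B and GABARAPL1 fell and PIK3C3 rose. Lysosomal genes were split, 19 up and 16 down of 43 (camera adjusted p = 0.642), with a median of 0, which was -0.10 with total-count scaling, and a mean of 0.11; CTSF, NAGPA and HEXA rose and GLA fell. ERK-dependent feedback and immediate early genes had 17 of 29 lower and 6 higher (camera adjusted p = 0.0238; adjusted p = 0.83 with an estimated correlation). JUN fell from 17804 ± 1331 to 2176 ± 238, IER3 and FOSL2 fell, and EPHA4 rose; IER3 lies within the row of TUBB. Interferon-stimulated genes had 24 of 40 lower and 7 higher (camera adjusted p = 0.00525; adjusted p = 0.741 with an estimated correlation). HLA-B and HLA-C, similar genes between which reads could be split, had log2 fold changes of -1.87 and -1.52, and SAMHD1 rose.

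**Figure D2:**
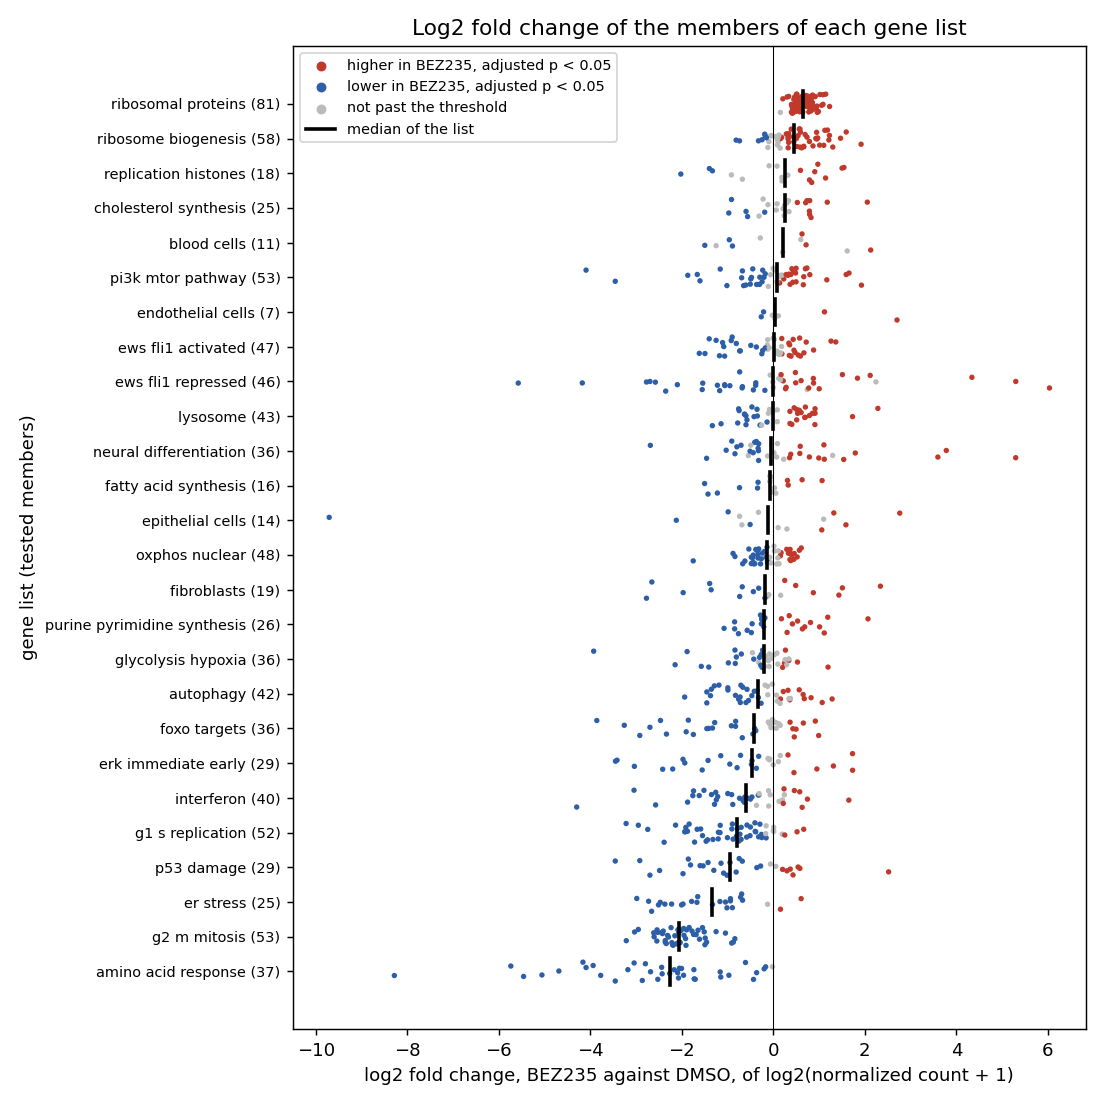
Log2 fold change (BEZ235 against DMSO, of log2(normalized count + 1)) of each tested member of 26 gene lists, coloured by whether it passed the threshold upwards (red), downwards (blue) or not (grey), with the median of each list as a black bar. Medians run from -2.26 for the ATF4 list to 0.64 for the ribosomal protein list.

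The 2 genes joined in the EWSR1-FLI1 fusion that defines most Ewing sarcomas changed little. Their rows count reads per gene, so the fusion transcript itself was not measured apart from unfused transcripts. EWSR1 had a log2 fold change of 0.14 (SE 0.056, limma adjusted p = 0.0441) with overlapping groups. The adjusted p was 0.113 without DMSO replicate 1, 0.168 without DMSO replicate 3, 0.12 without BEZ235 replicate 1, 0.149 without BEZ235 replicate 2 and 0.557 with total-count scaling, and ran from 0.00149 to 0.557 over all alternatives. FLI1 had one of -0.07 (SE 0.078, adjusted p = 0.428). Of 47 genes reported to be raised by the fusion, 17 rose and 18 fell (camera adjusted p = 0.962), with a median of 0.02, which was -0.07 with total-count scaling, and a mean of -0.12. Of 46 reported to be lowered by it, 17 rose and 21 fell (camera adjusted p = 0.55). The nuclear receptor NR0B1 fell from 54196 ± 5215 to 25064 ± 427, PPP1R1A and VRK1 fell, and PAPPA rose. NKX2-2, a homeodomain factor of Ewing cells, rose from 3154 ± 126 to 7561 ± 127. In the lowered list ACTA2, CDKN1A and CXCL8 fell and VIM, vimentin, rose from 210762 ± 30907 to 909967 ± 74421. ACTA2 overlaps its antisense gene, and the strand of the counts is unknown. MYC had a log2 fold change of 0.45 (SE 0.072) and CCND1 of -0.37 (SE 0.088). Neuronal genes rose for 13 and fell for 15 of 36 tested, or 14 and 15 adjusted over the list alone (camera adjusted p = 0.962), with a median of -0.05 and a mean of 0.31. NCAM1, a neural adhesion molecule, fell from 4734 ± 290 to 734 ± 30.7, NEFM and MAPT fell, and CHGA rose.

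Metabolic lists were not called by camera. Cholesterol synthesis and uptake genes had 9 of 25 up and 5 down (camera adjusted p = 0.128; 0.0295 without DMSO replicate 1), with TM7SF2, CYP51A1 and NSDHL up and STARD4 down. TM7SF2 rose from 2459 ± 95.7 to 10220 ± 229. Fatty acid synthesis genes had 6 of 16 down and 4 up (camera adjusted p = 0.512). ME1, ACSL3 and SREBF1 fell, SREBF1 with a log2 fold change of -1.22 (SE 0.064), and TMEM97 rose. SREBF2 had one of 0.08 (SE 0.081, adjusted p = 0.392), which was -0.02 without DMSO replicate 2. Glycolysis and hypoxia genes had 16 of 36 down and 6 up, or 14 and 6 adjusted over the list alone (camera adjusted p = 0.122; 0.044 without a filter). The growth factor VEGFA fell from 80039 ± 6070 to 18103 ± 1421, ERO1A and SLC2A3 fell and PFKM rose. Genes of purine and pyrimidine synthesis and the pentose phosphate pathway were split, 12 up and 14 down of 26. Their median was -0.20 and their mean 0.10 (camera adjusted p = 0.962). MTHFD1L and RPIA fell and IMPDH2 rose from 67535 ± 2506 to 154236 ± 7517. Nuclear genes of the respiratory chain had 26 of 48 down and 14 up, or 26 and 16 adjusted over the list alone (camera adjusted p = 0.269). CYCS, cytochrome c, fell from 183590 ± 5247 to 54639 ± 2824, NDUFS8 and NDUFB8 fell, and NDUFB5 rose.

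All 17 rows of the mitochondrial genome fell, with log2 fold changes from -2.64 to -1.03. Several short rows lie inside longer ones, such as 6888 to 7189 inside 5584 to 12142, so the 17 rows are not separate measurements. The row at 1670 to 5512, which covers MT-RNR2, MT-ND1 and MT-ND2, had the change of -2.64 (SE 0.155, limma adjusted p = 8.62e-08). The row at 5584 to 12142, from MT-CO1 to MT-ND4, had one of -2.13 (SE 0.128), and that of MT-CYB at 14761 to 15953 of -1.24 (SE 0.101).

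**Figure D3:**
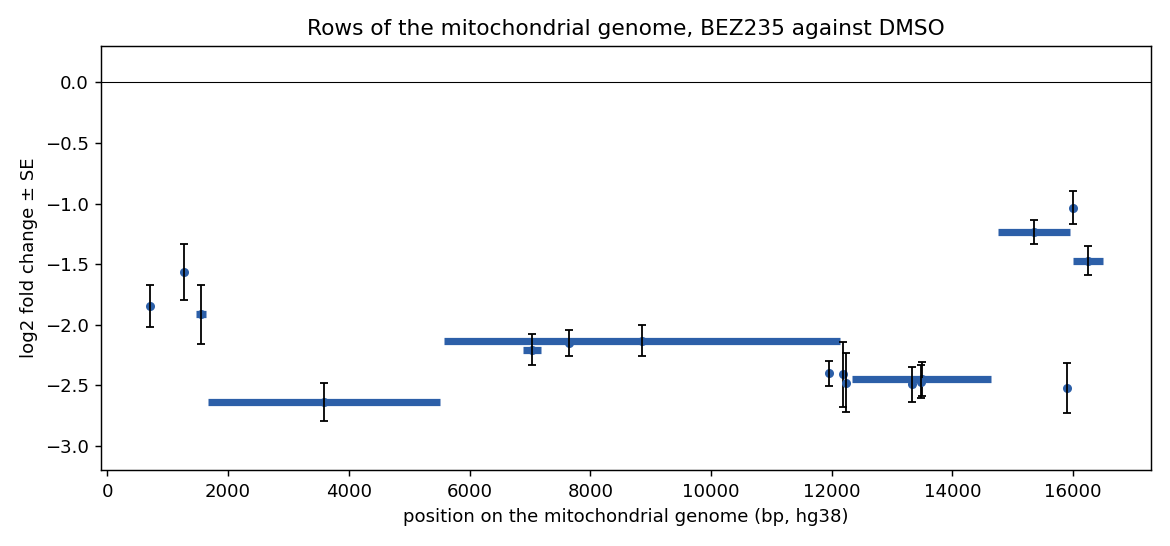
Log2 fold change (BEZ235 against DMSO) of the 17 rows on the mitochondrial genome against position (bp, hg38), with bars spanning each row and error lines of 1 SE. The values lie between -2.64 and -1.03.

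Marker lists of other cell types were measured in this cell line without assigning any. Blood markers had 3 of 11 up and 3 down, with a median of 0.21, a mean of 0.09 and a camera test directed downwards (camera adjusted p = 0.962). HBA1, HBA2 and LYZ rose, HBA1 from 558 ± 210 to 867 ± 41.2, and CD68 fell; HBA1 and HBA2 are near-identical copies. The log2 fold change of HBA2 was 0.63, or 0.27 without DMSO replicate 2, and its adjusted p was 0.0978, 0.0634 and 0.0947 without BEZ235 replicates 1, 2 and 3 (0.00446 to 0.141 over all alternatives). That of HBA1 was 0.72, or 0.36 without DMSO replicate 2, with an adjusted p of 0.0725 without BEZ235 replicate 3 (0.00148 to 0.103). That of LYZ was 2.13, or 1.20 without DMSO replicate 1, with adjusted p of 0.0774 without that library and 0.117 and 0.0868 without BEZ235 replicates 1 and 2 (0.0123 to 0.117). Epithelial markers had 4 of 14 up and 4 down (camera adjusted p = 0.962), with MUC1, CDH3 and EPCAM up and ESRP1 down. Fibroblast markers had 10 of 19 down and 6 up (camera adjusted p = 0.269), with ACTA2, TWIST1 and LUM down and MMP2 up. Endothelial markers had 2 of 7 up and 2 down (camera adjusted p = 0.962), with a median of 0.04, which was -0.06 with total-count scaling. ESAM rose and ENG fell by 0.26, and PLVAP, near the floor at 29.5 ± 19.0 against 7.31 ± 10.6, had a log2 fold change of 2.70 with overlapping groups, or 1.68 without DMSO replicate 2. Its adjusted p was 0.0939 and 0.0786 without DMSO replicates 2 and 3 and 0.0674, 0.159 and 0.0611 without BEZ235 replicates 1, 2 and 3 (0.00354 to 0.159 over all alternatives).

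In total camera called 11 of 26 lists, 2 up and 9 down, and fry called 19. With an estimated correlation 0 were called and 3 had an unadjusted p under 0.05. For the p53 list the estimated correlation was 0.012, close to the preset 0.01, yet its call was lost too. The size of the correlation alone cannot account for that loss. The other lists called had larger estimated correlations, up to 0.736 for the ribosomal protein list. The variant with an estimated correlation also takes its degrees of freedom from the 6 libraries, and the preset variant takes them from the far more numerous genes. A p above the threshold there is therefore not by itself evidence that a list did not move. The calls with the preset correlation still depend on that preset. The other splits of the 6 libraries into groups of 3 each mix the treatments. In them camera called 8 to 11 lists where limma called 0 genes. Part of the treatment difference stays between such groups, so these list calls are not calls without signal. For those of the 26 lists not given with both counts, the numbers adjusted over the list alone were the same as over all genes.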

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

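Total-count scaling was chosen after the data were seen, the other alternatives before. Over all alternatives the count of called genes ran from 14285 to 16102 and that of genes changed at least 2-fold from 5091 to 6895. Leaving out each library in turn gave 14285 to 15680 called genes and 10 to 13 lists. Of 121 genes that the naming rule selects, 115 kept direction and side of the threshold in all those of 17 alternatives that tested them. Genes that reach the filter in only 3 libraries, such as FGF21 and TAC1, were not tested when 1 of these was left out. EWSR1, HBA1, HBA2, LYZ and PLVAP lost their calls in some alternatives. SREBF2, not called, had values of -0.021 without DMSO replicate 2 (-0.021 to 0.144 over the libraries left out) and -0.014 with total-count scaling. Lists called fell from 11 to 0 with an estimated correlation and rose to 19 with fry, which compares no list with other genes. Correlation alone cannot be the cause for every list, since the variant with an estimated correlation also has far fewer degrees of freedom. Lists not called changed the sign of their test in some alternatives, and the cause was not tested; adjusted p with each library left out ran from 0.937 to 0.99 for the purine and pyrimidine list, 0.703 to 0.982 for the fusion-raised list, 0.926 to 0.982 for the neuronal and the endothelial lists and 0.913 to 0.982 for the blood list. The purine and pyrimidine list did so with quantile normalization (adjusted p = 0.971), the replicate block (0.963), edgeR (0.757), DESeq2 (0.74) and without DMSO replicate 2 (0.99) or BEZ235 replicates 1 (0.977), 2 (0.982) and 3 (0.937). The PI3K list did so with edgeR (0.995), DESeq2 (0.999) and fry (0.382), the endothelial list with a filter at 50 (0.951) and without DMSO replicate 2 (0.945) or BEZ235 replicate 2 (0.982), the blood list without DMSO replicate 1 (0.977), and the fusion-raised and neuronal lists without DMSO replicate 2 (0.913 and 0.945). Total-count scaling moved the share of calls that were higher from 49.9% to 43.7%. Depth limits genes near 3 reads, such as FGF21 and TAC1.

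The replicate numbers showed no sign of pairing the samples: correlations of deviations from the group means were -0.038, 0.023 and 0.044 for equal numbers, and not every library correlated best with its own number. With 3 libraries per group such correlations cannot exclude a pairing. With the replicate number as a block, 15917 genes were called instead of 15863 (7932 higher, 7985 lower, 6318 at least 2-fold) and 11 lists.

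The 6 libraries have 10 splits into groups of 3, the real split included, too few for a share under 0.05. The real split gave 15863 called genes (6303 at least 2-fold, 7912 higher, 7951 lower). The highest of the others gave 0 for each by limma, with up to 358 genes at an unadjusted p under 0.05. Only 1 of the 10 splits, the real split, was as large. Every other split mixes the treatments in both groups, so the treatment difference widens the spread within groups there. Few gene calls could come out of such splits, and they cannot decide whether the real calls arose by chance. For lists called, the real value was 11 and the highest other also 11, reached by 4 of the 10 splits with the real split included; the others called 8 to 11 lists.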

Other observations

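The gene groups below, the genes named beside them and the tests of scaling, poly(A) selection, transcription factor mRNAs and epithelial cells were chosen after the data were seen; the tests of transcript length, GC content and level and of the ESRP1 region were set out before their results were seen. Genes of the motile cilium, the beating cell projection, were more often higher than lower with BEZ235: 41 of 75 tested rose and 10 fell. The list was drawn up after RSPH1, RSPH4A, ENKUR and CIBAR2 had been seen among the rises; without them 37 of 71 rose and 10 fell, with a median log2 fold change of 0.54 (camera adjusted p = 0.000903; adjusted p = 0.143 with an estimated correlation). HYDIN of the central apparatus rose from 38.6 ± 12.8 to 281 ± 33.3 (SD, n = 3), the dynein gene DNAI3 from 107 ± 6.93 to 900 ± 54.5, and DNAH10 fell from 1830 ± 135 to 436 ± 32.6.

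A further group held translation factors and other genes outside the ribosomal protein list with a reported terminal oligopyrimidine tract. Through this motif mTOR controls translation of such mRNAs. In this group 21 of 22 tested rose and 0 fell, or 21 and 1 adjusted over the list alone (camera adjusted p = 8.28e-09, or 0.314 with an estimated correlation). The RNA-binding protein gene HNRNPA1 rose from 93918 ± 1327 to 372961 ± 20671 and the initiation factor gene EIF3A from 20380 ± 2207 to 57474 ± 3484. Mitochondrial ribosomal protein genes rose for 46 of 76 and fell for 20, or 46 and 22 adjusted over the list alone (camera adjusted p = 0.00245, or 0.445 with an estimated correlation). Cytoskeletal SRF targets rose for 8 and fell for 13 of 29 (camera adjusted p = 0.279). ACTG1 rose from 669966 ± 18414 to 4470990 ± 294635; this gene has pseudogenes, and whether its reads were separated from theirs is not known.

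The fall of the mitochondrial genome rows, with a median log2 fold change of -2.21, was weighed against 3 explanations. The choice between the scalings used is argued against: total-count scaling moved the median of all genes only from -0.001 to -0.096, and that of these rows to -2.30. All these scalings are relative, so a change in the amount of RNA per cell cannot be seen with them. A difference in poly(A) selection stays open. The replication-dependent histone genes had a median of 0.26 (SD 1.04), but they cannot decide this question. Some of them also make polyadenylated mRNAs, and their levels can change with DNA replication, for which 43 of 52 listed genes fell and 3 rose. How RNA was selected is not known either. Lower mRNA of mitochondrial transcription and maintenance factors stays open: their median was 0.17 (SD 0.58), but of 32 members 15 rose and 9 fell, with a lowest value of -1.05, and a fall in a single limiting factor would not need the others to move. Other effects of BEZ235 stay open too and were not tested.

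The rise of the ribosomal protein list, 4 of whose 81 members (EEF1A1, EEF1B2, EEF2 and TPT1) are not ribosomal proteins, was weighed against scaling and against transcript properties. With total-count scaling the median was 0.55, and with quantile normalization 0.35. The size of the rise thus depended on the scaling, and its direction did not change under these scalings, which are all relative. Other genes matched on transcript length, GC content and level (10 for each of 81, 179 different genes) had a median of 0.10. Random matched lists reached at most 0.44, below 0.64. The matched genes had a lower level, a median of 108617 against 372596, but the 54 other rows at or above the lower quartile of the list had a median of -0.21. The group with a terminal oligopyrimidine tract, of which 21 of 22 rose, was left out of both comparisons. The 54 rows included falling rows of the mitochondrial genome. With these choices the comparisons do not exclude a part played by level. An effect of BEZ235 on these mRNAs stays open as a hypothesis, and no mechanism was tested.

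The near-complete fall of ESRP1 was weighed against loss of its region and against other cells. The 20 tested rows within 1 Mb had a median log2 fold change of 0.34, with 10 up and 7 down, which argues against loss of a wide region; a change limited to ESRP1 stays open. The other 13 epithelial markers had a median DMSO level of 241.6 and a maximum of 1700, far below 18015, which argues against epithelial cells in the DMSO cultures. If synthesis had stopped at the start of treatment, the ratio of means of 816 over 16 h would need an mRNA half-life of at most 1.65 h. An effect of BEZ235 on ESRP1 stays open as a hypothesis, and no mechanism was tested.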
